A study of Homo sapiens with 12 samples.

How the data were processed

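The series holds 12 samples of MCF-7, an established breast cancer cell line, which per the labels was infected with lentivirus carrying a short hairpin RNA (shRNA) and selected for 6 to 8 days. The hairpin was a scrambled control (sh-C) or was directed against LSD1 (sh-LSD1), the histone demethylase encoded by KDM1A. RNA sequencing covers 2 libraries per group, and chromatin immunoprecipitation with sequencing (ChIP-seq) covers 1 library per group for each of LSD1, H3K4me1 and H3K4me2, plus 1 input per group. The labels give no batch, date or donor, and they do not say whether the RNA libraries of a group came from separate cultures.

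For RNA, the deposited table gives raw fragment counts per gene name, which the authors made with STAR 2.4.0i and featureCounts 1.5.0-p1 on 1 µg of ribosome-depleted RNA. Per the file header, counting was reverse-stranded and per fragment, exons with the same gene name in GENCODE release 26 lifted to hg19 were summed, and fragments with several alignments were not counted. The table has 58522 gene names, of which 26629 have no count in any library. Library totals were 20383187 and 16587328 in sh-C and 20457644 and 19164015 in sh-LSD1. For the chromatin samples, the authors aligned reads of 50 bp from fragments of 300 to 800 bp with BWA 0.7.12-r1039, called peaks with MACS2 2.1.1.20160309 and annotated them with HOMER 4.9.1, all on hg19. The 6 deposited peak lists give position, width and annotation in bp, and the peak-calling threshold is not stated. They hold no height, fold or p-value, because the column headed as a score repeats a position. Read depth is therefore unknown for the chromatin libraries, the inputs have no processed file, and ranking of peaks by strength was not possible. Listed starts lie 1 bp to the right of the start that the width implies, which was corrected before any overlap was counted; positions are printed as listed.

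Genes were tested with edgeR 4.0.16 in R 4.3.3. Genes passing filterByExpr defaults were kept, TMM factors were used, and a quasi-likelihood F test compared sh-LSD1 with sh-C at a Benjamini-Hochberg adjusted p under 0.05. All p-values of genes and lists are two-sided, and those of genes measure only the spread between these libraries. The standard error (SE) of a log2 change was taken from the F statistic. Levels are counts scaled to library size (CPM) with their SD over 2 libraries. For a gene with 1 to 3 counts over the 2 libraries of a group, the ratio of summed counts is given with its exact conditional 95% interval, and against a group with 0 counts the ratio is a lower bound against a floor of 3 counts over the group. Such intervals cover counting error only. A test on simulated counts with 200 changed genes recovered 43.3% of them at a fold of 1.5, 77.6% at a fold of 2 and 98.5% at a fold of 4. It called 8 unchanged genes among 154 calls. The changed genes were drawn from those with a mean of at least 1 CPM among 17366. In the data 37.9% of tested genes were called, so these rates need not hold there.

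Before the data were examined, 21 gene lists were fixed from textbook knowledge, together with the comparisons, the tests, the further settings and the genes to name. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 21 lists. The same test with an estimated correlation and the fry test were run beside it. With the preset correlation, the p of a list measures the spread over genes under that correlation, not the spread between libraries. With an estimated correlation the 4 libraries leave 2 residual degrees of freedom, and the smallest unadjusted camera p of any list was 0.112. A list not called by that setting is therefore no evidence against its change. Genes named in the text are KDM1A, GATA3, TRIM37, ESR1, FOXA1, CDH1 and VIM, the 8 largest rises and 8 largest falls among called genes with a mean of at least 1 CPM and no overlap between the groups, and up to 4 members of each list with the smallest p. Any gene named outside this rule is marked as chosen after its values were seen.

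Peak overlaps were counted from 1 bp and compared with 100 shuffles of the same peaks within their chromosomes. Shares carry 95% Wilson intervals, which cover counting error only. A gene's transcription start site (TSS) was the outermost 5′ end of its name in the count table, so promoters of inner transcripts are missed. Promoters were 1 kb either side of the TSS in 17319 tested genes with a single position. Fisher's exact test compared called with uncalled genes, adjusted over 10 tests. The covered length of H3K4me1 and H3K4me2 within 5 kb of the TSS was compared between sets of genes by 100000 permutations of gene labels. Neighbouring genes share promoters and genes are not independent replicates. These steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and bedtools 2.31.1, and figures were drawn with matplotlib 3.10.9.

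Alternatives for RNA were DESeq2 1.42.0, RLE and upper-quartile factors, no filter and a stricter filter, the replicate number as a block, each library left out in turn, limma voom and a test against a fold of 1.5. Alternatives for peaks were merging within 1 kb, overlap of 50% of a peak, promoters of 5 kb, Mantel-Haenszel odds ratios over 10 classes of expression, and genes called by DESeq2. Leaving out mitochondrial genes, leaving out peaks at satellite repeats and using only peaks wider than the smallest width were added after the data were seen. The planned stricter peak threshold and the planned naming of the strongest LSD1 peaks could not be carried out without a peak score.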

Results

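The series measured RNA by sequencing and LSD1, H3K4me1 and H3K4me2 occupancy by ChIP-seq in MCF-7 cells carrying a scrambled hairpin (sh-C) or a hairpin against LSD1 (sh-LSD1). LSD1 removes methyl groups from mono- and dimethylated lysine 4 of histone H3, the marks H3K4me1 and H3K4me2. RNA came from 2 libraries per group, with total counts from 16587328 to 20457644. Each antibody had 1 library per group, so differences between peak lists have no replicate error. According to its design text, the series asks how transcripts and the occupancy of LSD1 and both marks differ between control and knockdown cells.

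RNA of the hairpin's target, KDM1A (chromosome 1, 23345941 to 23410182, hg19), was lower in sh-LSD1. Its level went from 121 ± 7.5 CPM (SD, n = 2) in sh-C to 12.8 ± 0.75 CPM in sh-LSD1, so that 10.6% was left, a log2 change of -3.24 ± 0.14 (SE; edgeR adjusted p = 1.2e-15). GATA3 (chromosome 10, 8095567 to 8117161), a transcription factor of luminal breast cells, fell by 0.805 ± 0.14 on the log2 scale, from 626 ± 48.5 to 358 ± 3.4 CPM (SD, n = 2; edgeR adjusted p = 4.6e-05). TRIM37 (chromosome 17, 57059999 to 57184282), a ubiquitin ligase gene, fell by 0.77 ± 0.15, from 1050.0 ± 55.2 to 615 ± 56.7 CPM (SD, n = 2; edgeR adjusted p = 1.4e-04). VIM, which encodes the mesenchymal filament protein vimentin, rose by 2.996 ± 0.42 on the log2 scale but stayed low, at 0.27 CPM in sh-C and 2.39 CPM in sh-LSD1. Without sh-C replicate 1 the change of VIM was 4.201, since its sh-C libraries held 0.43 and 0.12 CPM. The oestrogen receptor gene ESR1 (415 and 394 CPM, adjusted p = 0.71) and the E-cadherin gene CDH1 (1279 and 1235 CPM, adjusted p = 0.82) did not pass the test, and without sh-C replicate 2 the log2 change of ESR1 went from -0.08 to 0.03. FOXA1, a luminal transcription factor, had a log2 change of -0.25 ± 0.13 with an adjusted p of 0.13, and without sh-C replicate 2 its adjusted p was 0.047. Tested against a fold of 1.5, the calls of GATA3 (adjusted p = 0.123) and TRIM37 (adjusted p = 0.199) ended.

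**Figure D1:**
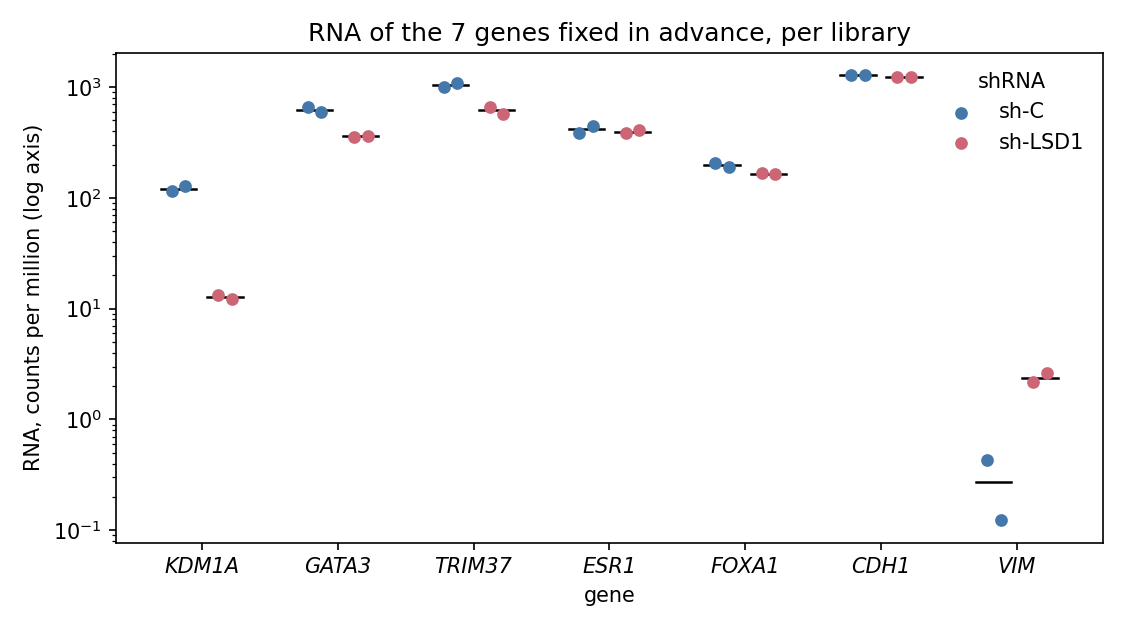
RNA levels (CPM, log axis) of the 7 genes fixed in advance, with 1 point per library and a line at the group mean, for sh-C (blue) and sh-LSD1 (red). KDM1A went from 121 to 12.8 CPM, and VIM rose from 0.27 to 2.39 CPM.

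Of 17366 tested genes, 3386 were higher and 3196 lower in sh-LSD1, and the changes were at least 2-fold for 1329 of the former and 1008 of the latter. Among the largest rises were LIX1L (chromosome 1, 145477085 to 145501670), from 0.58 to 24.8 CPM (log2 change 5.44 ± 0.24), the serine protease gene TMPRSS11E (5.28 ± 0.37) and the kinase gene DCLK2 (4.51 ± 0.33). Other rises started from a few counts in sh-C. HES7, a transcriptional repressor of the segmentation clock, went from 2 to 197 counts over the group, a ratio of 94.0 with a 95% interval of 25.7 to 781. TLR6, a receptor of innate immunity, went from 3 to 225 counts (ratio 71.5, 24.2 to 350.0), the cysteine protease gene CTSS from 3 to 118 (37.5, 12.5 to 185), CYTH4 from 3 to 77 (24.5, 8.07 to 121) and the glucose transporter gene SLC2A3 from 2 to 129 (61.5, 16.7 to 514). SLC2A3 has a close paralog, SLC2A14, and fragments aligning to several places were not counted. ABCA4, a retinal lipid transporter gene (chromosome 1, 94458391 to 94586688), fell by 6.155 ± 0.315 on the log2 scale, from 18.5 to 0.256 CPM. MUC5AC, a secreted mucin gene, fell by 5.49 ± 0.4, GABRP fell by 4.901 ± 0.46, PLEKHG4B by 4.69 ± 0.43 and SYNPO2 by 4.63 ± 0.285. ECEL1 went from 84 counts to 0 and was at least 29.4-fold lower. ABCC13 went from 184 to 3 counts, 64.3-fold lower (21.7 to 315), and PSG9, a member of a gene family of similar sequence, from 108 to 3, 37.7-fold lower (12.6 to 186). Single libraries weigh on these values, as HES7 had 0 and 2 counts in the sh-C libraries, CYTH4 had 3 and 0, TLR6 and CTSS had 1 and 2 each, and in sh-LSD1 ABCC13 had 3 and 0 and PSG9 1 and 2. For MUC5AC the log2 change was -4.695 without sh-C replicate 1 and -6.165 without sh-LSD1 replicate 1, which for GABRP gave -5.715. Without sh-LSD1 replicate 1 the count of lower genes was 2034, and without sh-LSD1 replicate 2 it was 2014. Testing against a fold of 1.5 left 1206 higher and 920 lower genes.

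Interferon-stimulated genes, which act in antiviral defence, rose together, with 46 of 47 tested members higher, none lower and a median log2 change of 1.97 (camera adjusted p = 8.2e-23). With an estimated correlation, which was 0.418 for this list against the preset 0.01, that adjusted p = 0.72. IFI27 rose from 7.26 to 124.5 CPM (4.08 ± 0.17), IFIT1 from 5.99 to 94.0 CPM (3.94 ± 0.19), IFI6 from 24.9 to 300.2 CPM (3.59 ± 0.16) and the helicase gene DDX60 from 8.13 to 80.0 CPM (3.29 ± 0.14). Without sh-C replicate 1 the change of IFIT1 was 4.58. STAT2, chosen after its value was seen as the member not called, had a log2 change of 0.13 ± 0.12. Replication-dependent histone genes fell together, with 0 of 49 higher and 40 lower at a median of -0.57 (camera adjusted p = 1.15e-11; adjusted p = 0.72 with an estimated correlation). HIST2H3D had a log2 change of -1.27 ± 0.13, HIST1H3D -1.14 ± 0.12, HIST1H4A -1.03 ± 0.14 and HIST1H2BF -0.999 ± 0.12, among copies whose sequences are close to each other, and without sh-LSD1 replicate 1 the list had 26 lower. Of 24 genes of cholesterol synthesis and transport, 15 rose and 0 fell (camera adjusted p = 8.3e-04; adjusted p = 0.72 with an estimated correlation). Without sh-LSD1 replicate 1 the higher genes were 8, and without sh-C replicate 2 1 gene was lower. STARD4, a sterol carrier gene, rose by 3.095 ± 0.16 on the log2 scale, the synthesis genes DHCR24 by 1.35 ± 0.14, FDFT1 by 1.34 ± 0.14 and HMGCS1 by 1.23 ± 0.145. In each of these 3 lists the counts adjusted over the list alone were equal to those over all genes. Tested against a fold of 1.5, 38 interferon-stimulated genes were higher, 6 histone genes lower and 5 cholesterol genes higher.

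Genes of other H3K4 demethylases and methyltransferases were lower as a list, with 3 higher and 13 lower of 24 (camera adjusted p = 0.0097; adjusted p = 0.73 with an estimated correlation). SMYD3 had a log2 change of -1.145 ± 0.15, KDM2B -0.84 ± 0.12, PAXIP1 -0.77 ± 0.13 and MEN1 -0.66 ± 0.13, and adjusted over the list alone 14 were lower. Without sh-LSD1 replicate 1 the list's adjusted p was 0.062, with 0 higher and 5 lower, without sh-LSD1 replicate 2 it had 0 higher and 9 lower and without sh-C replicate 1 it had 1 higher and 15 lower. By the fry test its adjusted p was 0.052. Neuronal targets of REST and CoREST, repressor proteins that work with LSD1, had 1 higher and 7 lower of 18 (camera adjusted p = 0.048; adjusted p = 0.72 with an estimated correlation). MAPK8IP1 had a log2 change of -1.70 ± 0.16, the sodium pump gene ATP1A3 -1.475 ± 0.22, the tubulin gene TUBB3 -1.09 ± 0.16 and CELSR3 -0.81 ± 0.12. This call ended without sh-C replicate 1 (adjusted p = 0.18, with 3 higher and 5 lower) and without sh-LSD1 replicate 1 (adjusted p = 0.070), and adjusted over the list alone the counts were again 1 and 7. Genes of NF-kB signalling and inflammation had 10 higher and 3 lower of 17 (camera adjusted p = 0.048; adjusted p = 0.73 with an estimated correlation), and 11 and 3 adjusted over the list alone. The chemokine gene CCL5 rose by 3.33 ± 0.25 on the log2 scale, BIRC3 by 1.995 ± 0.23 and TNFAIP3 by 1.68 ± 0.235, and TNFAIP2 had a change of -1.18 ± 0.16. The list's adjusted p was 0.051 without sh-C replicate 1, 0.057 without sh-C replicate 2 and 0.092 without sh-LSD1 replicate 2, where 6 were higher and 2 lower, as also under DESeq2. Without sh-C replicate 1 the change of CCL5 was 4.275. Mitochondrially encoded genes had 8 higher and 0 lower of 15, and 12 and 0 adjusted over the list alone (camera adjusted p = 0.012; adjusted p = 0.73 with an estimated correlation). MT-ND3 was at 499 ± 168 CPM in sh-C and 813 ± 85.0 CPM in sh-LSD1 (SD, n = 2), and its adjusted p was 0.146 under DESeq2. Mitochondrial genes took 7.58% and 10.3% of counts in the sh-C libraries and 11.9% and 16.2% in the sh-LSD1 libraries. The ribosomal RNAs MT-RNR1 and MT-RNR2 alone took 2.72% and 6.41% in sh-C and 6.13% and 10.7% in sh-LSD1, and the other mitochondrial genes 4.86% and 3.85% in sh-C and 5.80% and 5.44% in sh-LSD1. MT-RNR1, called higher (log2 change 1.246 ± 0.344), overlapped between the groups, at 6336 and 21220 CPM in the sh-C libraries and 19880 and 45480 CPM in the sh-LSD1 libraries. Its adjusted p was 0.401 under DESeq2, 0.0669 against a fold of 1.5 and 0.28 without sh-LSD1 replicate 2, where its change was 0.531. Without sh-C replicate 1 the change was 0.625, and without sh-C replicate 2 it was 2.364. Without sh-LSD1 replicate 2 the list's adjusted p was 0.055. The 8 higher genes became 13 with no filter on counts, 1 without sh-LSD1 replicate 2, 3 without sh-LSD1 replicate 1 and 14, with 1 lower, without sh-C replicate 1, and by the fry test the list's adjusted p was 0.078. With mitochondrial genes left out, the neuronal list had an adjusted p of 0.053 and the NF-kB list of 0.056, while 3424 genes were higher and 3158 lower. Tested against a fold of 1.5, the list of H3K4 enzymes had 0 higher and 1 lower, the neuronal list 0 and 4, the NF-kB list 4 and 1 and the mitochondrial list 0 and 0. KDM2B (adjusted p = 0.0505), PAXIP1 (0.162), MEN1 (0.516) and CELSR3 (0.0813) lost their calls at that fold.

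**Figure D2:**
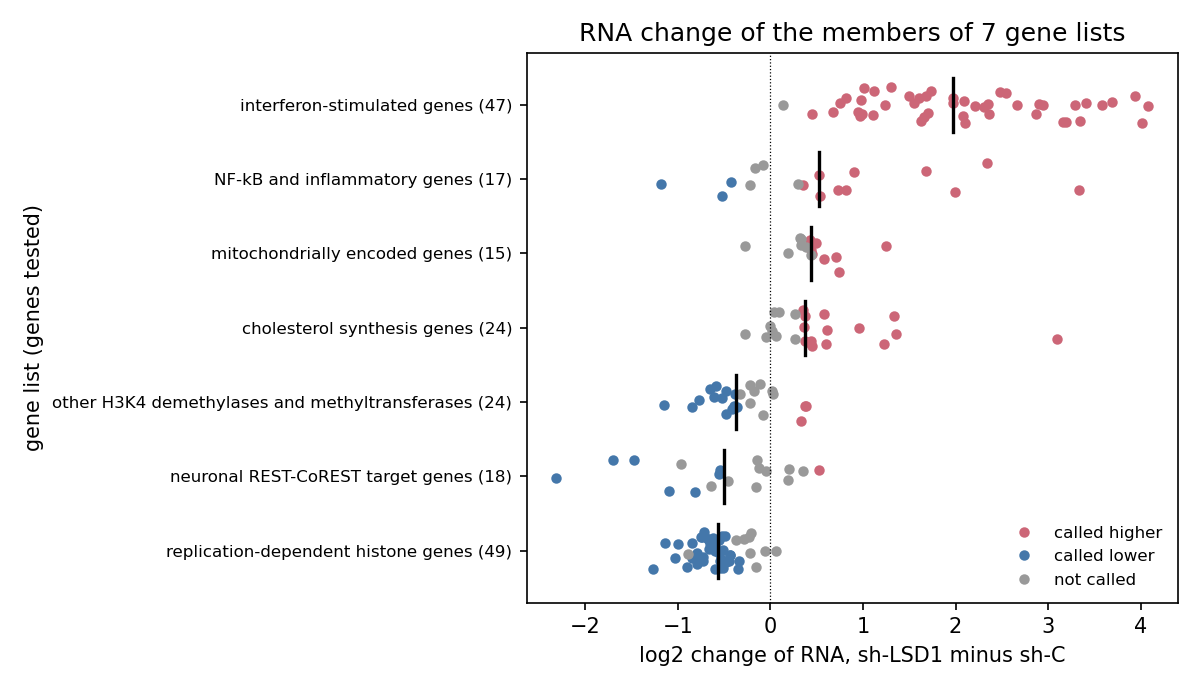
Log2 change of RNA (sh-LSD1 minus sh-C) of each tested member of the 7 lists called with the preset correlation, coloured by the call of the gene, with a black line at the list's median. The interferon-stimulated genes have a median of 1.97 and the replication-dependent histone genes of -0.57.

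The other 14 lists were not called by camera, but the fry test called the LSD1 complexes (lower, adjusted p = 0.042) and the oestrogen-induced (0.022), hypoxia (0.042) and immune lists (0.023; all higher). Subunits of LSD1 complexes had 3 higher and 7 lower of 25 (adjusted p = 0.18), and 3 and 10 adjusted over the list alone. KDM1A itself, the hairpin's target, is among them at -3.24, so the knockdown itself is part of this list's fall. MTA2 had a log2 change of -1.21 ± 0.13, CTBP2 of -0.73 ± 0.12 and PHF21A of 0.95 ± 0.12. Oestrogen-induced genes had 14 higher and 12 lower of 39 (adjusted p = 0.53), and 16 and 12 adjusted over the list alone. PDZK1, a scaffold protein gene, rose from 5.94 to 90.2 CPM (3.92 ± 0.15), the chemokine gene CXCL12 rose by 3.38 ± 0.15 and MYBL1 by 2.03 ± 0.13, while the keratin gene KRT13 fell by 3.56 ± 0.25. Luminal markers had 2 higher and 8 lower of 24 (adjusted p = 0.20; the same 2 counts adjusted over the list alone), with MUC1 at 1.73 ± 0.14, TFF3 at 1.63 ± 0.22 (2.47 without sh-C replicate 1), ELF3 at -1.37 ± 0.13 and AGR2 at -0.86 ± 0.14. Basal markers had 6 higher and 5 lower of 17 (adjusted p = 0.53; 6 and 6 adjusted over the list alone), with the laminin genes LAMC2 at 1.64 ± 0.15 and LAMA3 at 1.19 ± 0.13. Mesenchymal genes had 9 higher and 6 lower of 24 (adjusted p = 0.45; 10 and 6 adjusted over the list alone), with PLAUR at 1.55 ± 0.15, fibronectin (FN1) at 1.04 ± 0.13, LOXL2 at -1.06 ± 0.14 and TGFBI at -1.15 ± 0.16. Epithelial junction genes had 10 higher and 5 lower of 34 (adjusted p = 0.53; 10 and 6 adjusted over the list alone), with a median of -0.015 and a mean of 0.13. Cell cycle and DNA replication genes had 5 higher and 5 lower of 45 (adjusted p = 0.95; 5 and 4 adjusted over the list alone), with a median of 0.002 and a mean of -0.013, and the cyclin gene CCNE1 fell by 1.86 ± 0.19. Targets of p53 had 5 higher and 8 lower of 30 (adjusted p = 0.66; the same 2 counts adjusted over the list alone), and the kinase gene PLK2 fell by 2.12 ± 0.14. Unfolded protein and amino acid stress genes had 8 higher and 10 lower of 27 (adjusted p = 0.53; 8 and 11 adjusted over the list alone), with CHAC1 at -2.27 ± 0.20 and DDIT4 at -1.79 ± 0.14. Hypoxia and glycolysis genes had 9 higher and 2 lower of 25 (adjusted p = 0.15; the same 2 counts adjusted over the list alone), with PFKFB4 at 1.105 ± 0.15 and PFKFB3 at -1.91 ± 0.13. This list also holds SLC2A3 (log2 change 5.78, from 2 counts in sh-C), and its median change was 0.159 against a mean of 0.377. Immediate-early genes had 6 higher and 4 lower of 21 (adjusted p = 0.66; 7 and 4 adjusted over the list alone), and MYC fell by 1.03 ± 0.13. Among markers of other cell types, 1 of 4 tested fibroblast genes was higher and 1 lower (adjusted p = 0.95; median -0.15, mean 0.16), 2 of 2 immune genes were higher (adjusted p = 0.11) and 2 of 5 endothelial genes were higher and 3 lower (adjusted p = 0.66), and adjusted over the list alone these counts were the same. Under DESeq2 fibroblast markers had 1 higher and 0 lower, immune markers 0 and 0 (ITGAM adjusted p = 0.0785, CSF1R 0.190) and endothelial markers 0 and 1. The collagen gene COL1A1 rose from 10.2 to 31.9 CPM and the integrin gene ITGAM from 0.66 to 1.75 CPM.

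Other settings moved several of these counts by over 1.5 times. Under DESeq2 p53 targets had 5 genes higher and 5 lower, under voom fibroblast markers had 1 and 0, and with the strict filter endothelial markers had 1 and 2. Tested against a fold of 1.5, the LSD1 complexes had 1 higher and 2 lower, luminal markers 2 and 2, oestrogen-induced genes 5 and 6, junction genes 3 and 1, mesenchymal genes 7 and 3 and basal markers 6 and 2. By that test cell cycle genes had 0 and 1, p53 targets 1 and 3, unfolded protein genes 0 and 3, hypoxia genes 4 and 1, immediate-early genes 1 and 3, fibroblast and immune markers 1 and 0 each and endothelial markers 1 and 1. The calls of CTBP2 (adjusted p = 0.223) and AGR2 (0.0558) ended at that fold. Without sh-C replicate 1 the LSD1 complexes had 5 genes higher and 9 lower, luminal markers 5 and 9, basal markers 6 and 3, fibroblast markers 2 and 0 and endothelial markers 2 and 1. Without sh-C replicate 2 luminal markers had 4 and 9, junction genes 10 and 8, cell cycle genes 8 and 6, immediate-early genes 4 and 7, immune markers 1 and 0 and endothelial markers 1 and 3. Without sh-LSD1 replicate 1 luminal markers had 2 and 5, junction genes 9 and 2, cell cycle genes 7 and 3, p53 targets 1 and 3, unfolded protein genes 5 and 5, fibroblast and immune markers 1 and 0 each and endothelial markers 1 and 2. Without sh-LSD1 replicate 2 the LSD1 complexes had 1 and 4, luminal markers 2 and 4, junction genes 6 and 1, basal markers 6 and 3, cell cycle genes 3 and 2, p53 targets 4 and 4, unfolded protein genes 4 and 8, hypoxia genes 6 and 1, fibroblast and immune markers 1 and 0 each and endothelial markers 1 and 1. The camera direction of the cell cycle list turned to higher without sh-C replicate 2 (adjusted p = 0.77) and without sh-LSD1 replicate 1 (adjusted p = 0.46), and the immediate-early (adjusted p = 0.98) and fibroblast lists (adjusted p = 0.70) turned to lower without sh-C replicate 2. Some medians changed sign. Without sh-C replicate 1 the median of the junction list was 0.066, of the cell cycle list -0.057 and of the fibroblast list 0.173. Without sh-LSD1 replicate 1 the junction list had 0.076, and without sh-LSD1 replicate 2 the cell cycle list had -0.077.

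LSD1 peaks numbered 33548 in sh-C and 16072 in sh-LSD1, a ratio of 0.48, and covered 2.03 and 0.937 Mb. The median width was 47 bp in both lists, the smallest width listed, which 60.0% and 63.3% of peaks had. Within 1 kb of a TSS lay 2.47% of sh-C peaks (95% interval 2.31 to 2.65) and 1.36% of sh-LSD1 peaks (1.19 to 1.55). Of the sh-C peaks, 549 or 1.64% (1.51 to 1.78) were overlapped by a sh-LSD1 peak, against 0.0709% of shuffled peaks, and of the sh-LSD1 peaks 3.40% (3.13 to 3.70) were overlapped by a sh-C peak. Without peaks at satellite repeats these shares were 0.516% and 1.14%. In sh-C, 15.1% of LSD1 peaks (14.7 to 15.5) lay at an H3K4me2 peak and 5.40% (5.16 to 5.64) at an H3K4me1 peak, 6.09 and 9.79 times the shares of shuffled peaks. In sh-LSD1, 4.50% of LSD1 peaks (4.19 to 4.83) lay at an H3K4me2 peak and 4.11% (3.82 to 4.43) at an H3K4me1 peak, 1.47 and 3.09 times the shares of shuffled peaks. The 549 sh-C peaks overlapped in sh-LSD1 lay at sh-C H3K4me2 peaks less often than the other 32999, at 8.56% against 15.2% (Fisher's exact test, odds ratio 0.52, p = 5.8e-06). At sh-C H3K4me1 peaks the shares were 3.64% and 5.42% (Fisher's exact p = 0.070). Without satellite peaks, which made up 68.5% of the 549, the direction turned. Of the sh-C peaks not at satellites, 173 were overlapped by any sh-LSD1 peak, satellite or not. At sh-C H3K4me2 peaks lay 27.2% of these 173 against 15.5% of the other 32395 (Fisher's exact test, odds ratio 2.04, p = 8.2e-05). At sh-C H3K4me1 peaks the shares were then 9.83% and 5.51% (odds ratio 1.87, Fisher's exact p = 0.019).

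H3K4me1 peaks numbered 27769 in sh-C and 64886 in sh-LSD1, a ratio of 2.34, and covered 13.2 and 33.1 Mb. H3K4me2 peaks numbered 69267 and 87071, a ratio of 1.26, and covered 68.7 and 85.6 Mb. Of the sh-C H3K4me1 peaks, 54.1% (53.5 to 54.7) were overlapped in sh-LSD1, and of the sh-C H3K4me2 peaks 87.2% (87.0 to 87.5). In the other direction, 22.9% of sh-LSD1 H3K4me1 peaks and 68.4% of sh-LSD1 H3K4me2 peaks were overlapped in sh-C. H3K4me2 peaks lay within 1 kb of a TSS in 23.3% of cases in sh-C and 19.1% in sh-LSD1, and H3K4me1 peaks in 3.29% and 2.64%. Sites of sh-C LSD1 peaks carried H3K4me1 peaks in 5.40% of cases in sh-C and 8.09% (7.81 to 8.39) in sh-LSD1, and H3K4me2 peaks in 15.1% and 16.8% (16.4 to 17.2), while the share of shuffled peaks at H3K4me1 rose from 0.551% to 1.345% and at H3K4me2 from 2.48% to 3.07%.

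**Figure D3:**
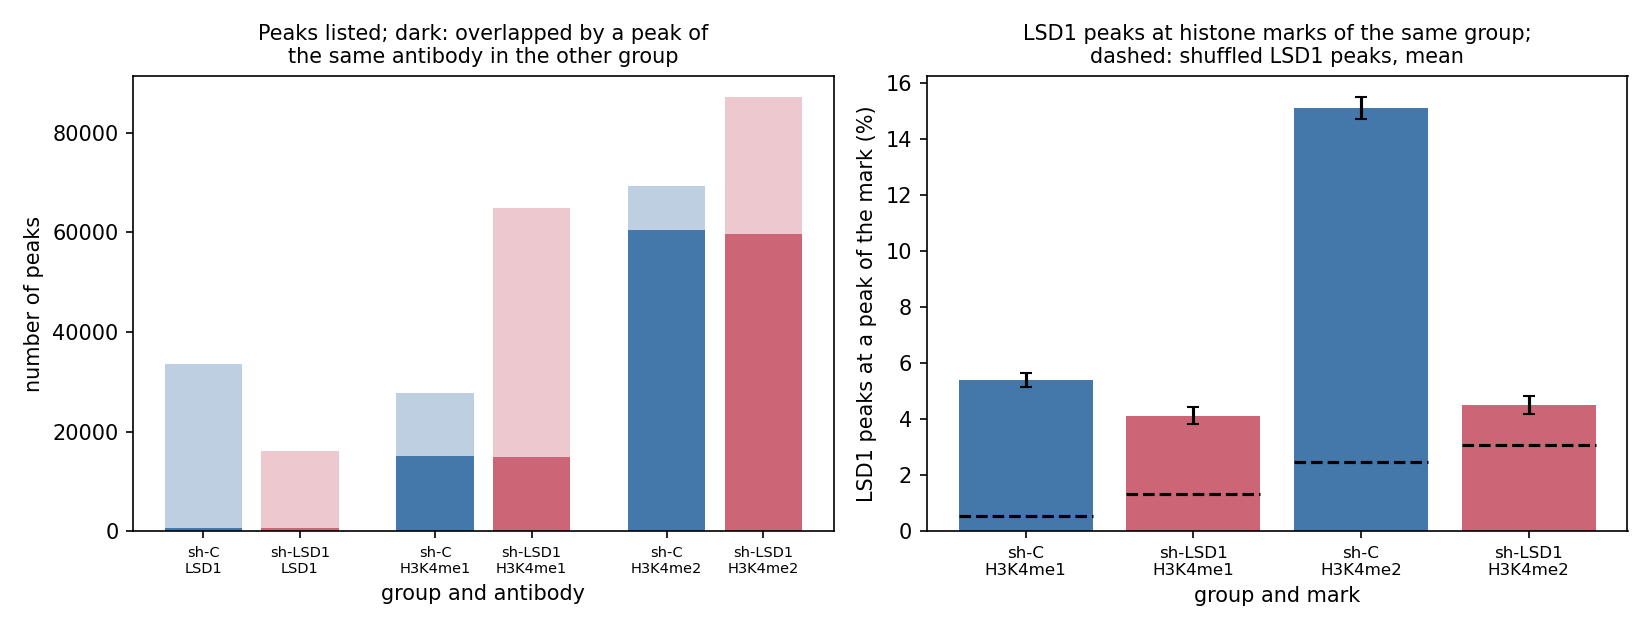
Left, the number of peaks per list, with the darker part overlapped by a peak of the same antibody in the other group. Right, the share of LSD1 peaks (percent, with 95% Wilson intervals) at a histone peak of the same group, with the mean of shuffled peaks as a dashed line. At H3K4me2 the share is 15.1% in sh-C and 4.50% in sh-LSD1.

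At VIM, a sh-C LSD1 peak of 172 bp (chromosome 10, 17270333 to 17270503, hg19) lay in exon 1, in the 5′ UTR, 74 bp from the TSS, and no LSD1 peak was listed within 5 kb of the gene in sh-LSD1. An H3K4me2 peak over the VIM TSS (17269499 to 17270566) was listed in sh-LSD1, whereas the nearest H3K4me2 peak in sh-C began 1443 bp away. TRIM37 had 6 LSD1 peaks in or within 5 kb of the gene in sh-C and 0 in sh-LSD1, the nearest in intron 1, 718 bp from the TSS (chromosome 17, 57183491 to 57183564). The 5 Mb window with TRIM37 (chromosome 17, 55 to 60 Mb), chosen after the data were seen, held 218 sh-C and 200 sh-LSD1 LSD1 peaks. The medians over all windows were 39 and 16, so the window was crowded with calls in both lists. GATA3 had 1 LSD1 peak in sh-C, of the smallest width of 47 bp, in intron 5 (chromosome 10, 8111662 to 8111707), and 0 in sh-LSD1, with 9 and 11 H3K4me2 peaks. ESR1 had 20 LSD1 peaks in sh-C and 4 in sh-LSD1, FOXA1 had 1 and 0, and CDH1 and KDM1A had 0 in both lists. The FOXA1 peak and the 2 sh-C peaks nearest the ESR1 TSS were also 47 bp wide. Absence from the sh-LSD1 list does not set a site apart, as 1.64% of all sh-C LSD1 peaks were overlapped in sh-LSD1. H3K4me1 peaks at ESR1 numbered 30 in sh-C and 59 in sh-LSD1, at CDH1 12 and 22, and at TRIM37 14 and 23. Of the 16 genes with the largest rises and falls, GABRP alone had a sh-C LSD1 peak within 1 kb of the TSS (chromosome 5, 170189845 to 170189897, 457 bp away, intergenic).

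Genes with higher RNA gained H3K4me2 around their TSS more than other genes. Within 5 kb of the TSS, the length covered by H3K4me2 peaks changed by 515 ± 12 bp (SE over 3386 genes) in genes with higher RNA, by 162 ± 5.2 bp in 10740 genes not called and by 22.6 ± 9.8 bp in 3193 genes with lower RNA. The difference from uncalled genes was 352 bp for higher and -140 bp for lower genes (permutation test, adjusted p = 1e-05 for each, the smallest the permutations can give). For H3K4me1 the differences were 67.5 and -53.4 bp (permutation test, adjusted p = 1e-05 for each, the smallest possible). Among genes with no H3K4me2 promoter peak in sh-C, 118 of 696 higher genes or 16.95% (14.35 to 19.9) had one in sh-LSD1, against 239 of 2767 uncalled genes or 8.64% (7.65 to 9.74; Fisher's exact test, odds ratio 2.16, adjusted p = 1.3e-08). The gain was also more frequent in lower genes, at 11.7% (odds ratio 1.40, adjusted p = 0.04999). With expression levels matched this odds ratio was 1.09 (adjusted p = 0.67), and that of higher genes was 1.795 (adjusted p = 1.26e-05). With promoters of 5 kb the gain had odds ratios of 1.67 in lower (adjusted p = 5.69e-04) and 1.745 in higher genes (adjusted p = 1.13e-04). With genes called by DESeq2 they were 1.90 (adjusted p = 8.78e-04) and 2.83 (adjusted p = 1.01e-11). Loss of an H3K4me2 promoter peak was found in 35 of 2586 lower genes or 1.35%, against 0.73% of uncalled genes (odds ratio 1.87, adjusted p = 0.025). With genes called by DESeq2 the odds ratio was 1.42 (adjusted p = 0.33). With expression levels matched it was 2.46 (adjusted p = 1.05e-04) and with promoters of 5 kb 1.65 (adjusted p = 0.028). For higher genes the odds ratio of loss was 0.71 (adjusted p = 0.40). H3K4me1 promoter peaks were gained by 9.26% of higher and 7.77% of uncalled genes (odds ratio 1.21, adjusted p = 0.025) and by 6.61% of lower genes (odds ratio 0.84, adjusted p = 0.057). The smaller gain of lower genes passed with promoters of 5 kb (odds ratio 0.79, adjusted p = 1.8e-05) and with expression levels matched (0.80, adjusted p = 0.023). Losses of H3K4me1 had odds ratios of 0.93 for higher and 0.96 for lower genes (adjusted p = 0.80 and 0.85), and with promoters of 5 kb the odds ratio was 0.70 for higher genes (adjusted p = 8.5e-04) and 1.10 for lower genes (adjusted p = 0.33).

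**Figure D4:**
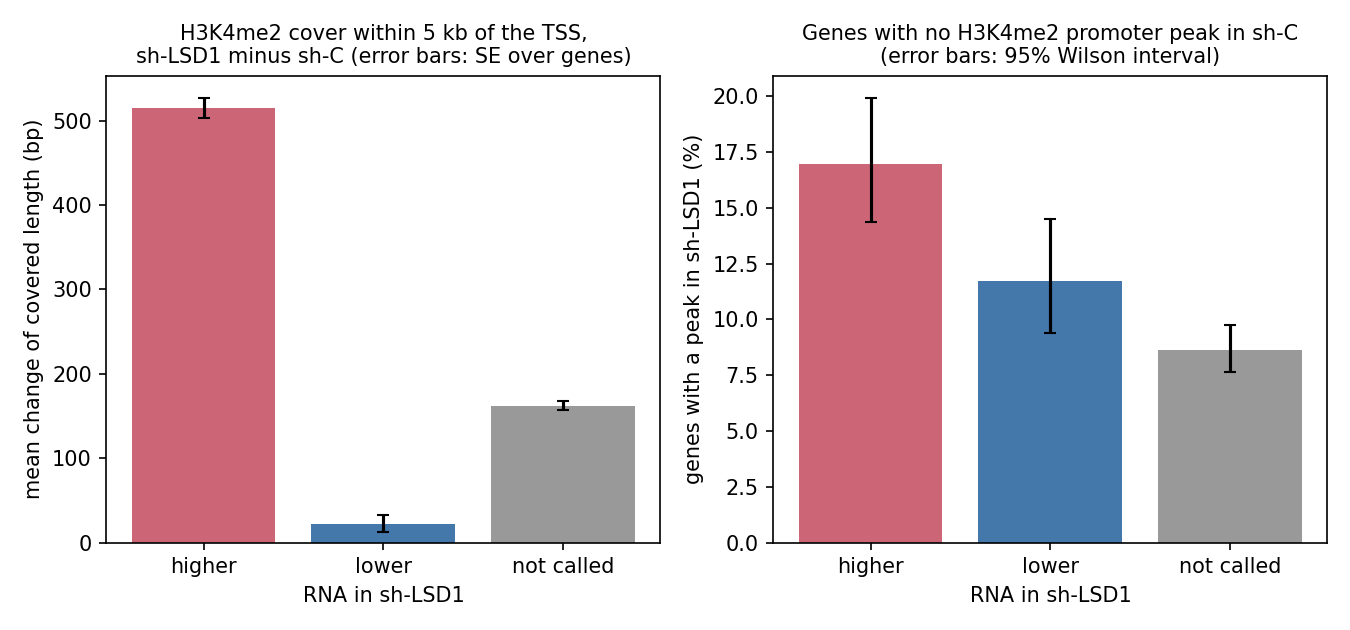
Left, the mean change in the length covered by H3K4me2 peaks within 5 kb of the TSS (bp, sh-LSD1 minus sh-C, SE over genes) for genes with higher, lower or uncalled RNA. Right, the share of genes without an H3K4me2 promoter peak in sh-C that have one in sh-LSD1 (percent, 95% Wilson interval), which is 16.95% for higher genes and 8.64% for uncalled genes.

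A sh-C LSD1 peak lay at the promoter of 630 tested genes, and at 129 in sh-LSD1. It was present at 132 of 3386 higher genes or 3.90% (3.30 to 4.604) and at 404 of 10740 uncalled genes or 3.76% (odds ratio 1.04, Fisher's exact test, adjusted p = 0.80). In lower genes the share was 2.94% (94 of 3193; odds ratio 0.78, adjusted p = 0.057). With promoters of 5 kb, the odds ratio was 1.18 for higher genes (adjusted p = 0.0048) and 0.73 for lower genes (adjusted p = 4.68e-06), and with expression levels matched it was 0.74 for lower genes (adjusted p = 0.023).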

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

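The tests in this part of immune markers, of library scaling, of the hairpin, of wider LSD1 peaks alone, of the share of sh-LSD1 LSD1 peaks at sh-C peaks and of sh-LSD1 LSD1 peaks at H3K4me2 and H3K4me1 peaks were chosen after the results were seen, and the others before.

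The annotation of peaks by repeat class, a column that the comparisons do not use, differed between the groups beyond counting error. Among LSD1 peaks, satellite repeats made up 7.05% in sh-LSD1 (6.66 to 7.46) and 2.92% in sh-C (2.75 to 3.11), LTR elements 8.70% and 7.05%, and DNA elements 4.01% and 3.46%, while LINE elements went from 23.9% in sh-C to 21.2% in sh-LSD1. Among H3K4me1 peaks, SINE elements made up 17.2% in sh-LSD1 and 13.6% in sh-C, LINE elements 12.4% and 10.6%, and DNA elements 3.95% and 3.48%, while LTR elements went from 6.65% to 5.94%. Among H3K4me2 peaks, SINE elements made up 11.8% in sh-LSD1 and 8.63% in sh-C, LTR elements 5.60% and 4.83%, and DNA elements 2.39% and 1.99%, while LINE elements went from 10.8% to 9.95%.

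The rise of interferon-stimulated genes in sh-LSD1 is the widest change of a list, with 46 of 47 genes higher. Library scaling is argued against, because a scaling factor moves all genes alike, while the median log2 change of the list lay 1.98 above that of the other tested genes, and its lower quartile of 1.18 lay above their upper quartile of 0.351. RNA from immune cells is argued against as the reason for the rise by the sum of all 15 immune markers. It was 179 counts in sh-C and 290 in sh-LSD1, a ratio of 1.51 after scaling to library totals (95% interval 1.25 to 1.83). This ratio lay under the lower quartile of the list's folds (2.27). The rise of the markers was in CSF1R and ITGAM, as the other 13 went from 41 to 37, and its source stays open, though DESeq2 called neither gene (adjusted p = 0.190 and 0.0785) and CSF1R lost its call without sh-C replicate 2 (adjusted p = 0.0752) and without either sh-LSD1 library (0.111 each). Infection with a lentivirus carrying a hairpin, and selection, were shared by both groups. An effect of this hairpin's sequence or of an unequal dose cannot be told apart from loss of LSD1. The libraries carry 1 shRNA label against LSD1 and no second hairpin or rescue. The knockdown, which left KDM1A RNA at 10.6% of its sh-C level, therefore stays open as a hypothesis.

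LSD1 peaks of both groups rarely overlapped, although the sh-LSD1 list held 16072 peaks. Calls at the smallest width were overlapped less often than wider ones, at 0.41% against 3.48%, as the hypothesis that they are mostly background foretold. This cannot decide it, because narrower peaks offer less length to overlap under any cause. In sh-C these smallest LSD1 peaks lay at H3K4me2 peaks in 11.1% of cases and at H3K4me1 peaks in 3.74%. Shuffled sh-C LSD1 peaks of all widths lay there in 2.48% and 0.551%, so the smallest calls were not placed as shuffled peaks are. Among wider peaks alone the share of sh-C peaks overlapped in sh-LSD1 was still 2.92%, under the 50% set after the values were seen. The smallest peaks are therefore not the whole reason. Loss of LSD1 from its sites would leave a subset of the sh-C sites, yet 3.40% of the sh-LSD1 peaks lay at sh-C peaks. Whether sites were lost or missed by a weaker library, with the remaining calls mostly background, stays open, since sh-LSD1 LSD1 peaks lay at H3K4me2 peaks 1.47 times as often as shuffled peaks but at H3K4me1 peaks 3.09 times as often, against 6.09 and 9.79 times for sh-C.

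H3K4me1 peaks were 2.34 times as many in sh-LSD1. For a more sensitive sh-LSD1 library alone, the bound set beforehand was that at least 90% of the widest 10% of sh-C H3K4me1 peaks are found again. The share was 85.1% (83.7 to 86.3), under that bound, with width standing in for strength as the lists hold no score. For H3K4me2 it was 99.9%, but of wider peaks (1884 to 14876 bp against 755 to 6394 bp). Wider peaks are overlapped more easily, so the shares of the 2 marks cannot be compared. For a gain at sites that had held LSD1, peaks of sh-LSD1 alone were to lie at sh-C LSD1 peaks more often than peaks of both groups. They lay there less often (odds ratio within 4 classes of width 0.43, 0.39 to 0.46). This cannot decide the question, because peaks of both groups were picked by a sh-C H3K4me1 peak. At such peaks sh-C LSD1 peaks lay 9.79 times as often as shuffled peaks. A gain at sites that had held LSD1 therefore stays open. A change of H3K4me1 brought about by the knockdown at sites away from the listed LSD1 peaks stays open as an untested hypothesis, and so does a mixture of library quality with such a change.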

How the results depend on the processing

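Most of the 1429 values computed under alternatives were unlikely to turn, so their number says little about stability. Counts of genes or lists and shares of overlap have no other side of no change. Another 1320 values belong to named genes, mostly picked by a small p or a large change. Of all 1429 values, 7 lay on the other side of no change. Of these, 4 were the odds ratios of sh-C LSD1 peaks kept in sh-LSD1 against the others at histone peaks. Without satellite peaks, which made up 68.5% of the kept peaks, these went from 0.52 to 2.04 (sh-C H3K4me2), from 0.51 to 2.07 (sh-LSD1 H3K4me2), from 0.66 to 1.87 (sh-C H3K4me1) and from 0.87 to 2.72 (sh-LSD1 H3K4me1). No call of a named gene or list turned. The other 3 values, which passed no threshold in either setting, were ESR1 (0.03) and COL5A1 (-0.10) without sh-C replicate 2 and the odds ratio of H3K4me1 loss in lower genes with 5 kb (1.10). Beside these values, the camera direction of 3 uncalled lists turned with a library left out, and medians of 5 uncalled lists changed sign, among them p53 targets (-0.033 to 0.007 without sh-LSD1 replicate 1) and immediate-early genes (0.046 to -0.007 without sh-C replicate 2 and -0.06 without sh-LSD1 replicate 1). The replicate block gave 1 higher and 12 lower genes for the H3K4 enzymes and 5 and 5 for p53 targets. Among all genes, 2 had calls in opposite directions with all libraries and without sh-LSD1 replicate 2. Leaving out mitochondrial genes or satellite peaks and keeping only wider peaks were chosen after the data were seen. Genes higher in sh-LSD1 numbered 2325 to 3469 under DESeq2, RLE, upper-quartile, voom, both filters and the replicate block, and 2349 to 3429 with a library left out. Genes lower numbered 2207 to 3269 under the same settings, and 2014 to 3322 with a library left out, the lowest without either sh-LSD1 library. With a fold of 1.5 tested, 1206 were higher and 920 lower, since the test asks for more. A library left alone in its group is assumed to vary like the others. The replicate numbers did not pair the libraries (correlation of deviations -0.022 within a number), and the replicate block gave 3153 higher and 2891 lower genes, a KDM1A change of -3.24 and 7 called lists. With the fry test 9 lists were called, and the cause was not tested. With mitochondrial genes left out 4 were called by camera, as the mitochondrial list was then absent. The neuronal and NF-kB lists only crossed the threshold, from a camera adjusted p of 0.048 each to 0.053 and 0.056. With an estimated correlation 0 were called, by a test with little power on its 2 residual degrees of freedom. Of 102 named genes, 25 changed their side of the threshold under some alternative, in 50 of 1320 values, 21 of them with a fold of 1.5.

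Merging, wider peaks and satellites left the ratios of peak numbers within 1.5 times. Requiring overlap of 50% of a peak gave 1.24% of sh-C and 2.725% of sh-LSD1 LSD1 peaks shared, 39.85% of sh-C H3K4me1 and 82.4% of H3K4me2 peaks found again, and 4.83%, 14.6%, 7.26% and 16.2% of sh-C LSD1 peaks at sh-C H3K4me1, sh-C H3K4me2, sh-LSD1 H3K4me1 and sh-LSD1 H3K4me2 peaks. Peaks wider than the smallest width gave 2.92% and 6.61%, 55.05% and 87.0%, and 7.36%, 20.9%, 11.05% and 23.2% in that order. Without satellite peaks, 0.516% of sh-C and 1.14% of sh-LSD1 LSD1 peaks were shared, since most shared peaks were satellites. At promoters, 5 kb gave LSD1 odds ratios of 1.18 for higher and 0.73 for lower genes, 0.79 for H3K4me1 gain in lower genes and 0.70 for H3K4me1 loss in higher genes. Matching expression gave 0.74 for LSD1 in lower genes, 0.80 for H3K4me1 gain in lower genes and 1.09 for H3K4me2 gain in lower genes, and DESeq2 calls gave 1.42 for H3K4me2 loss in lower genes; the causes were not tested. Stricter peak thresholds were not run, as the lists hold no score. In simulated data with 200 changed genes 77.6% of changes of 2-fold were recovered, and the depth of the chromatin libraries is unknown.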

Other observations

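Tests in this part of H3K4me2 cover at gene lists, of LSD1 at mesenchymal genes and of satellite repeats, and the list of sensors, the windows and the genes named, were chosen after the data were seen. Those of small-RNA genes, of endogenous retrovirus names and of LSD1 at interferon-stimulated genes were chosen after the rise of the interferon-stimulated genes was seen, but before their own results.

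Several genes that sense foreign or double-stranded RNA and DNA were higher in sh-LSD1, with 7 of 10 tested members higher and 0 lower in a list that shares members with the interferon-stimulated genes and so is no separate evidence of their rise. IFIH1 and DDX58, also among the interferon-stimulated genes, rose from 16.1 to 69.2 CPM and from 19.9 to 66.4 CPM, EIF2AK2 from 134 to 253 CPM and TMEM173 (STING) from 3.99 to 9.73 CPM, while MAVS was at 295 and 269 CPM (adjusted p = 0.47). The TLR3 counts were 2 and 1 in sh-C and 16 and 23 in sh-LSD1. Interferon genes themselves stayed too low to test. IFNL1 had 3 and 1 counts in the sh-C libraries and 14 and 9 in the sh-LSD1 libraries, IFNL3 had 2 and 2 and then 8 and 5, and IFNB1 had 1 and 0 and then 0 and 1. Of the receptor genes, IFNAR2 rose by 0.59 ± 0.14 on the log2 scale and IFNAR1 fell by 0.55 ± 0.12.

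H3K4me2 cover around the interferon-stimulated genes was longer in sh-LSD1. Within 5 kb of the TSS it went from a mean of 2152 to 3200.0 bp and was longer at 39 of 47 genes, 845 bp beyond the change at other tested genes (permutation test, adjusted p = 7e-05 over 7 lists). Cholesterol genes gained 458 bp (adjusted p = 0.001), mesenchymal genes, whose RNA list was not called, 325 bp (adjusted p = 0.016) and replication-dependent histone genes, whose RNA fell, 317 bp (adjusted p = 0.001) beyond other genes by the same permutation test. LSD1 peaks did not mark the interferon-stimulated genes, as a sh-C LSD1 promoter peak was listed at 1 of 47, IFIT1 (2.13% against 3.64% of other genes; odds ratio 0.58, Fisher's exact p = 1), and so few peaks leave open whether the odds differ. A sh-C LSD1 promoter peak was listed at 4 of 24 mesenchymal genes or 16.7%, VIM among them (odds ratio 5.33, Fisher's exact p = 0.010, adjusted p = 0.072 over 7 lists). The luminal markers were close to this, with 3 of 24 or 12.5% (odds ratio 3.80, Fisher's exact p = 0.055, adjusted p = 0.193). Such peaks therefore do not set the mesenchymal genes apart from the luminal ones. Since genes with higher RNA gained H3K4me2 in general, the 46 higher interferon-stimulated genes were also compared with the 3340 other higher genes. Their gain was 562 bp larger (permutation test, p = 1e-05, the smallest possible). Within 5 classes of the size of the RNA change, of which the highest held 33 of the 46, it was 458 bp larger (permutation test, p = 0.00011). Why they gained more was not tested.

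Another hypothesis was that lower RNA of small-RNA processing genes goes with the antiviral response. Of 10 such genes 3 were lower and 0 higher. Both parts of the outcome set beforehand for the hypothesis failed. The list was not called lower by camera (adjusted p = 0.19 over 3 lists, and 0.73 with an estimated correlation), and 30% of its genes were lower where over 33.3% were needed. It stays open only because a missed threshold does not show that the genes did not fall. The interval of the 30% (10.8 to 60.3) held both the 33.3% and the 18.4% of all tested genes that were lower. AGO2, the slicing Argonaute, fell by 0.916 ± 0.13 on the log2 scale (324 to 172 CPM), XPO5 by 0.45 ± 0.12 and DROSHA fell by 0.355 ± 0.12, while DICER1 was at 241 and 194 CPM (adjusted p = 0.073). Endogenous retrovirus genes were tested as a source of double-stranded RNA, and of 4 tested genes with such names 0 were higher and 1, ERV3-1, was lower (Fisher's exact p = 1 for higher genes by edgeR), too few to decide, since the table counts no repeat copies.

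LSD1 peaks found in both groups may reflect pile-up of reads at satellite repeats, which made up 68.5% of the sh-C peaks overlapped in sh-LSD1 (64.5 to 72.2) and 1.83% of those of sh-C alone (1.69 to 1.98). The 4 windows of 5 Mb with the most sh-LSD1 LSD1 peaks lay on chromosomes 1 (105 to 110 Mb), 3 (60 to 65 Mb), 17 (55 to 60 Mb) and 20 (50 to 55 Mb), in arms known for amplified segments in MCF-7. Their 5.85% of sh-LSD1 LSD1 peaks is high by the way they were chosen. Of the other lists they held 2.21% of sh-C LSD1 peaks, 2.53% of sh-C and 1.64% of sh-LSD1 H3K4me1 peaks, and 0.94% and 0.90% of H3K4me2 peaks, and the window on chromosome 17 holds TRIM37.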
